A study of Mus musculus with 8 samples.

How the data were processed

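Whole uterus was taken from 8 C57BL/6J mice on the morning of day 4.5 of pseudopregnancy, per the labels' protocols, and total RNA of each mouse was labelled with biotin and hybridised to its own array. Per the labels, the 4 exposed mice breathed aerosol for 3 hours a day at 2 puffs per minute from a device set to 245 °C, during 4 weeks of 5 days before mating and then daily until collection, and the 4 sham mice breathed room air. Groups were taken from the treatment stated for each sample.

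The authors deposited 1 table of log2 expression values with 22206 probe sets and 8 columns. The log2 scale is read from the range of the values, 2.75 to 13.6 on each array, and is not given in the sources used here. Partek is named per the submitters' processing notes, without a version, and background correction, summarisation and scaling are not given in the sources used here. The sorted deposited values of the 8 arrays differ by at most 0.0198 log2 units, so the columns had been brought to a common distribution and were used without further normalization. Such scaling sets a change shared by all genes to 0. No scan date or batch is given in the sources used here, and signal over background could not be assessed because a background level per probe set was not used here.

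Gene symbols came from the platform annotation, in which 19572 probe sets carry 1 symbol, 0 several and 2634 none. Of these symbols, 0 had to be updated against the RefSeq gene table of assembly GRCm38.p6, used for names alone, and list genes under older symbols were matched through it where an older symbol belonged to 1 gene. For the 55 symbols on more than 1 probe set, the one with the highest mean over all arrays was kept, giving 19505 genes. Areg, which was to be named, is not measured under its symbol. No genome build is named in the sources used here, so no coordinates are given.

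Differences, exposed minus sham, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) without covariates, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A fold is 2 raised to the size of the log2 difference. Of 41 gene lists, 40 with at least 5 measured members (23 pathways and 17 cell types) were tested with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated per list and with fry. The erythrocyte list had too few members and was not tested. Fry gave 0 lists past an adjusted p of 0.05, with direction or without. Scores are the mean log2 value of a list in each mouse, compared by exact two-sided permutation over the 70 assignments of mice to groups, which cannot give a p below 0.0286.

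Genes to be named were the 12 higher and 12 lower genes of smallest p (as fewer than 24 passed adjustment), leaving out predicted genes, olfactory and vomeronasal receptors and small RNAs, together with up to 4 members of smallest p from each list and 13 genes fixed by name, 12 of which were measured. This gave 175 genes, of which the text prints examples. The groups, tests, gene lists and this rule were fixed before the data were examined, as were the alternatives, except for the 3 settings that leave out several mice. Chosen after the values were seen were also the clock contrast (the mean of 9 clock output genes minus the mean of 3 opposing genes), the tests on adipocyte markers and on the ratio of SDs, and the correlation of list scores. The ribosome assembly list was written after Nolc1, Urb1, Rrp12 and Yrdc had been seen low, and leaves those 4 out. Genes outside the rule in the closing section were chosen after their values were seen.

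Alternatives comprised quantile normalization, median centring, filters at the 25th and 50th percentile of mean expression, eBayes with a trend, with trend and robust estimation, or no moderation, array weights, the replicate number as a block, other set tests, the mean of all probe sets of a gene, the median over markers, a correlation distance, and leaving out each mouse in turn. On simulated arrays with the means and SDs of these probe sets and 200 of them changed, limma's test of exposed against sham recovered 51.9% of 1.5-fold, 85.0% of 2-fold and 98.5% of 4-fold changes over 20 rounds. With no change, 1134 probe sets reached an unadjusted p under 0.05 on average and camera called 0.1 lists per round. Genes were simulated as independent, so the list result does not cover genes that vary together, as those of these uteri do.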

Results

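Gene expression was measured on arrays in whole uterus from 8 pseudopregnant C57BL/6J mice, an inbred strain, on day 4.5 of pseudopregnancy. Pseudopregnancy, which follows mating to a vasectomised male, gives a uterus under the hormones of early pregnancy with no embryo in it. The exposed group comprised 4 mice that inhaled aerosol from an electronic cigarette, made from propylene glycol and vegetable glycerin with 24 mg/mL nicotine, and the sham group comprised 4 mice that breathed room air. The comparison asks whether inhaled aerosol alters uterine gene expression around the time at which the uterus becomes receptive to an embryo. Each array came from 1 mouse, and the number of arrays limits the precision of every value. Values are log2 expression, and group values are means ± SD over 4 mice unless stated.

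Of the genes with the smallest p-values, Slc26a7, an anion exchanger, stood 2.32-fold higher in exposed uteri (8.40 ± 0.35 against 9.61 ± 0.49, sham first). Further genes with higher means were Me1, the cytosolic malic enzyme that yields NADPH (1.51-fold), Htr2a, a serotonin receptor (1.61-fold), Pot1a, a telomere-binding protein (1.43-fold), Steap3, a metalloreductase (1.38-fold), and Tslp, an epithelial cytokine (1.34-fold). Lower means were found for Rrp12 (1.63-fold), Nolc1 (1.45-fold) and Urb1 (1.43-fold), which act in the nucleolus in ribosome assembly, and for Fjx1 (1.53-fold), Spsb1 (1.44-fold) and Retnlg, a transcript of neutrophils (1.83-fold). The 4 exposed values of each of these genes lay on one side of the 4 sham values. None of them passed limma's test after Benjamini-Hochberg adjustment over all 22206 probe sets (adjusted p = 0.838 for each), so no single gene can be called changed over the whole array.

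Across the whole array, limma placed 0 probe sets past an adjusted p of 0.05, and 1203 at an unadjusted p under 0.05, where 1110 would be obtained by chance. Of these 1203, 647 had higher and 556 lower means after exposure. Adding a minimum change of 1.5-fold left 112 probe sets, 69 higher and 43 lower, and this count depends on single mice: without exposed mouse 1 it was 462, 209 higher and 253 lower, and without exposed mouse 4 it was 59. All 4 exposed values exceeded all 4 sham values at 307 probe sets and lay below them at 300, together 2.73% of the array against 2.86% by chance. Differences were small in general, with 98.9% of probe sets within 1.5-fold.

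Genes of the circadian clock formed the group with the most members past the test. Of 18 measured members, 6 passed as higher and 1 as lower when p-values were adjusted over the list alone. That adjustment does not cover the other lists tested, and 0 members passed over all probe sets. Higher were Per3, a period gene (2.48-fold, 8.27 ± 0.12 in sham and 9.57 ± 0.82 in exposed mice), and Rora (1.41-fold). So were the transcription factors Dbp (1.85-fold) and Hlf (1.78-fold) and the repressors Nr1d1 (1.68-fold) and Nr1d2 (1.65-fold). Arntl, which encodes the activator BMAL1, was lower by 0.66 on the log2 scale. Limma's adjusted p over the list alone ran from 0.00711 for Hlf and Nr1d1 to 0.0408 for Rora. Per1, also a period gene, differed by 0.04 ± 0.14 (SE) and was 1 of the 11 members that did not pass. The list as a whole was higher with camera (mean change 0.30, adjusted p = 0.000484), which ended with an estimated correlation (adjusted p = 0.707). The mean over the list was 8.10 ± 0.03 in sham and 8.39 ± 0.20 in exposed mice, all 4 exposed mice above all 4 sham mice (exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.381 after adjustment over 40 lists). Exposed mouse 2 lay highest, 0.54 above the sham mean, and exposed mouse 1 lowest, 0.06 above it. The labels place collection in the morning for both groups and give no hour.

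**Figure D1:**
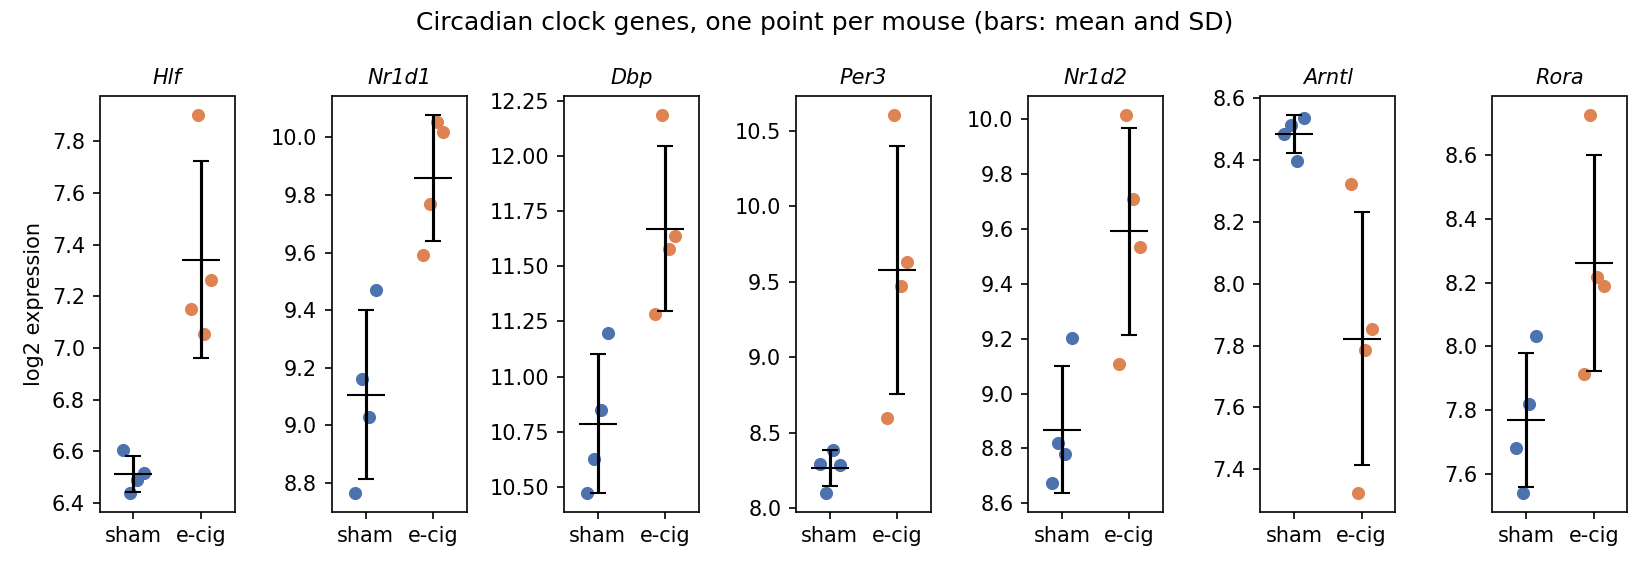
Log2 expression (vertical axis, own scale per panel) of the 7 circadian clock genes that passed limma's test adjusted over the list alone, in sham (blue) and exposed (orange) mice; each point is 1 mouse and the bars give mean and SD. Per3 stood at 8.27 ± 0.12 in sham and 9.57 ± 0.82 in exposed mice, and Arntl was lower in exposed mice.

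Genes of foreign compound metabolism, including targets of the aryl hydrocarbon receptor, were also higher as a list. Of 19 members, 15 had higher means and 0 passed when adjusted over the list alone. Aox3 (2.66-fold) and Aox1 (1.63-fold), both aldehyde oxidases, and Fmo1, a flavin monooxygenase (1.39-fold), had the smallest p-values, with adjusted p = 0.0636 over the list alone in limma. Cyp1a1, the classical target of the receptor, was dim on every array (4.55 ± 0.17 against 4.91 ± 0.23) and 1.28-fold higher. Camera gave an adjusted p of 0.00549 for the list, and the adjusted p was 0.707 with an estimated correlation. The list mean was 6.85 ± 0.10 in sham and 7.09 ± 0.08 in exposed mice, again without overlap (exact permutation p = 0.0286, 0.381 after adjustment). Cyp2e1, a member that fat cells express too, reached 7.20 and 7.81 in exposed mice 1 and 2 against 5.86 to 6.43 in the other 6. The adipocyte marker score was also highest in those mice (0.57 and 0.91 above the sham mean). The score of the foreign compound list was 0.180 and 0.199 above the sham mean in exposed mice 1 and 2, and 0.207 and 0.359 in exposed mice 3 and 4. The higher list mean therefore does not rest on the 2 mice with high adipocyte scores.

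Camera gave 5 lists as lower. Components of the mitochondrial respiratory chain were lower in 27 of 29 members (mean change -0.19, adjusted p = 2.11e-06, and adjusted p = 0.865 with an estimated correlation), with Cycs, which encodes cytochrome c, 1.39-fold lower and Ndufa1 1.46-fold lower. Proliferation genes were lower in 28 of 29 members (mean change -0.28, adjusted p = 0.000484, and adjusted p = 0.865 with an estimated correlation), among them Ccne2 (1.55-fold) and E2f1 (1.35-fold), which act in entry into S phase. Collagen and matrix genes were lower in 27 of 35 members (mean change -0.17, adjusted p = 0.000611, and adjusted p = 0.749 with an estimated correlation), with Col6a3 1.53-fold and Loxl1, a collagen and elastin cross-linking enzyme, 1.64-fold lower. Progesterone-responsive genes were lower in 17 of 24 members (mean change -0.28, adjusted p = 0.0273, and adjusted p = 0.749 with an estimated correlation), including Fkbp5 (1.57-fold), Sgk1 (1.80-fold) and Sox17 (1.52-fold). Smooth muscle markers were lower in 15 of 20 members (mean change -0.11, adjusted p = 0.0275, and adjusted p = 0.749 with an estimated correlation), with Synpo2 1.23-fold and Synm 1.32-fold lower. In each of these 5 lists 0 members passed adjusted over the list alone.

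Exposed mice 2 and 4 had the lowest scores of the exposed mice in all 5 lists. Relative to the sham mean, the proliferation score was -0.60 and -0.93 in them, -0.02 in exposed mouse 3 and 0.43 in exposed mouse 1. The respiratory chain score was -0.36 and -0.41 relative to sham in mice 2 and 4, and 0.0045 and 0.02 in mice 1 and 3. Without mice 2 and 4, a setting chosen after the data were seen, the mean change of the proliferation list was 0.209, which comes from exposed mouse 1, and that of the respiratory chain list 0.014. The collagen list mean was 9.40 ± 0.03 in sham and 9.23 ± 0.18 in exposed mice (exact permutation p = 0.0286, 0.381 after adjustment), with exposed mouse 2 at -0.44 relative to the sham mean and exposed mouse 1 at -0.0352, next to sham mouse 2 at -0.0341. Without exposed mouse 2, camera's adjusted p was 0.0546 for both the collagen and the proliferation list, with mean changes of -0.083 and -0.172. Without exposed mouse 4, the mean change was -0.061 for proliferation (camera adjusted p = 0.434) and -0.111 for the respiratory chain (camera adjusted p = 0.00438). The progesterone-responsive and smooth muscle lists each kept their call in 4 of the 8 fits that leave out 1 mouse, with the smallest mean changes, -0.160 and -0.0455, without exposed mouse 2.

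**Figure D2:**
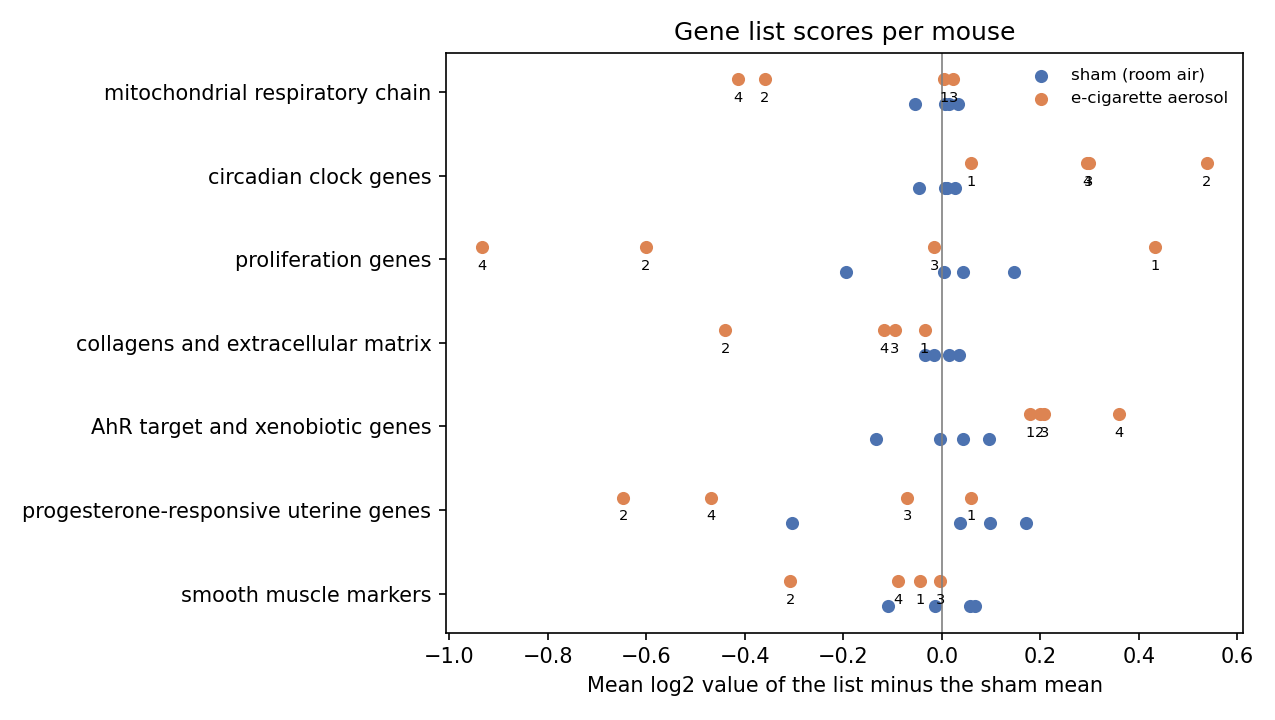
Mean log2 value of each of the 7 gene lists past camera's test, relative to the sham mean (horizontal axis), with 1 point per mouse, sham in blue and exposed in orange with the mouse number. Exposed mice 2 and 4 lie at -0.36 and -0.41 for the respiratory chain, whereas all 4 exposed mice exceed the sham mice for clock and foreign compound genes.

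Of the 41 measured members of the implantation and receptivity list, those with the largest differences were Ptgs2 (-0.87 ± 0.25, SE), Lifr (0.68 ± 0.27), Fkbp5 (-0.65 ± 0.25), Lpar3 (-0.62 ± 0.47, named after its values were seen) and Sox17 (-0.61 ± 0.26), none of which passed adjusted over the list alone. Without exposed mouse 4 the difference was -0.13 for Lpar3 and -0.31 for Sox17. Lif, the cytokine of the glands that is required for implantation, was 7.34 ± 0.22 in sham and 7.23 ± 0.23 in exposed mice, and Hbegf, an epidermal growth factor family ligand, was 6.62 ± 0.22 and 6.68 ± 0.18. The difference between groups was 0.33 ± 0.20 (SE) for Pgr, the progesterone receptor, 0.17 ± 0.12 for Esr1, the oestrogen receptor, -0.40 ± 0.18 for Ihh, -0.11 ± 0.11 for Hoxa10, -0.18 ± 0.12 for Msx1, -0.25 ± 0.15 for Foxa2, 0.18 ± 0.21 for Bmp2 and -0.35 ± 0.29 for Muc1. Ltf, the oestrogen-responsive lactotransferrin, varied most among the genes of this paragraph (8.56 ± 2.38 and 7.65 ± 1.18), with sham mouse 4 at 11.67. Without sham mouse 4 the difference was -0.0352 for Muc1, 0.0359 for Bmp2, 0.12 for Ltf and -0.0430 for Hoxa10. It was 0.142 for Pgr and 0.0537 for Esr1 without exposed mouse 2. Without exposed mouse 4 it was -0.130 for Foxa2 and -0.266 for Ihh, and without sham mouse 3 it was -0.0757 for Msx1. The implantation and receptivity list, with 16 of 41 members higher and 25 lower, did not pass camera (mean change -0.11, adjusted p = 0.107), nor did the oestrogen-responsive list (-0.02, 0.818, with a mean change of 0.194 without sham mouse 4) or the decidualization list (-0.09, 0.465).

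Genes of prostaglandin synthesis went both ways, 9 higher and 11 lower (camera adjusted p = 0.465), and 0 passed adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, was 1.82-fold lower (6.57 ± 0.49 against 5.70 ± 0.39), while Hpgds, a prostaglandin D synthase, was 2.50-fold higher (log2 difference 1.32 ± 0.42 SE) and Ptger4, a prostaglandin E receptor, 1.43-fold higher. Their adjusted p over the list alone was 0.0563 in limma. Luminal epithelium markers, 8 higher and 12 lower, did not pass (mean change -0.14, camera adjusted p = 0.155), and the member of smallest p was Cldn7 (log2 difference -0.49).

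Integrins, chemokines and JAK-STAT genes did not pass camera as lists. The study's publication is recalled to discuss these families, so their direction is not independent evidence. Its text was not used here, so these lists do not test what it reports. Mean changes were 0.02 for 24 integrins, -0.03 for 56 chemokines and receptors and 0.00675 for 42 JAK-STAT genes, with camera adjusted p of 0.931, 0.884 and 0.932, and 0 members of any passed adjusted over the list alone. The members with the smallest p-values were Itga7 (1.29-fold lower) and Itgb8 (1.71-fold higher), Ccr3 (log2 difference -0.58) and Cxcl12 (1.36-fold higher), and Ghr (1.41-fold higher) and Lifr (1.60-fold higher).

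Single members passed adjusted over the list alone in lists that did not pass camera. This adjustment does not cover the number of lists. Of 40 lists tested, 4 held such a member, the clock list included, and some would hold one by chance. Me1 was higher among 36 oxidative stress genes (adjusted p = 0.0233 in limma). Tslp, dim at 5.11 in sham and 5.54 in exposed mice (array median 7.08), was higher among 29 inflammatory mediators (adjusted p = 0.0432 in limma). Retnlg and Ccr3, the eotaxin receptor of eosinophils, were both lower among 14 neutrophil and eosinophil markers (adjusted p = 0.0179 in limma). Ccr3 was dim too (4.74 in sham and 4.16 in exposed mice). Camera gave adjusted p of 0.336, 0.592 and 0.404 for these lists, whose mean changes were -0.06, -0.04 and -0.11, and 0 of these genes passed over all probe sets. The mean of the neutrophil and eosinophil list rests largely on Retnlg and Ccr3, as the median change of its members was -0.013.

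Of 17 cell type scores, 0 reached an exact permutation p under 0.05 (smallest 0.0857, for neutrophil and eosinophil markers), which does not show that the make-up of the uteri was alike. With the median over markers in place of the mean, the neutrophil and eosinophil score differed by 0.018 (exact permutation p = 0.714). Smooth muscle markers passed camera, as given above, and adipocyte markers were highest in 2 exposed mice. Mean changes were 0.17 for gland, 0.13 for endothelium, 0.14 for lymphatic endothelium, 0.36 for adipocyte, 0.11 for T and B cell, 0.05 for natural killer cell, 0.05 for pancreas and gut, and 0.03 for oviduct and ciliated cell markers. They were -0.02 for stroma, -0.20 for macrophage and monocyte, -0.05 for dendritic cell, -0.05 for mesothelium, -0.04 for ovary and -0.0039 for neuron and glia markers. Single mice carry much of these values. The mean was -0.0751 for gland and 0.0267 for T and B cell markers without exposed mouse 4, 0.177 for adipocyte and -0.0291 for macrophage and monocyte markers without exposed mouse 2, and 0.0373 for endothelium markers without sham mouse 4. Among the pathway lists not yet named, mean changes were -0.14 for interferon-stimulated genes (-0.0105 without exposed mouse 2), -0.08 for immediate early genes, -0.08 for aldehyde and alcohol dehydrogenases, -0.10 for cholesterol synthesis, -0.03 for glucocorticoid-responsive genes, -0.0040 for the unfolded protein response, 0.0043 for hypoxia-responsive genes and 0.02 for nicotinic acetylcholine receptors. Across the 33 lists that did not pass, camera's adjusted p ran from 0.0553 to 0.966, and the list mean, median and test differed in sign in 11 (gland, stroma, mesothelium, natural killer cell, ovary, pancreas and gut, neuron and glia, chemokine, JAK-STAT, glucocorticoid and hypoxia lists).

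The main axis of variation between the mice was not shown to follow exposure. The first principal component carried 38.6% of the variance and set exposed mice 4 and 2 apart from the other 6, and a difference of 21.0 between the group means on it did not pass (exact permutation p = 0.257). Correlations with the other arrays averaged 0.977 for exposed mouse 4 and 0.982 for exposed mouse 2, against 0.986 to 0.987 for the rest. Distances between mice of different groups exceeded those within groups by 0.965 on average, a value that 10 of the 35 ways of dividing the mice reach, the real groups included (exact one-sided permutation p = 0.286). This separation turned negative without any 1 of the 4 sham mice (-0.178 to -2.20) and was 6.83 without exposed mouse 1. With a sham mouse left out, pairs of exposed mice outweigh pairs of sham mice in the within-group mean. As exposed mice varied more, this lowers the value whichever sham mouse is left out. The sign change therefore does not show that the separation depends on single sham mice. The SD between mice had a median of 0.134 in sham and 0.176 in exposed mice and was larger in the exposed group for 65.8% of probe sets.

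**Figure D3:**
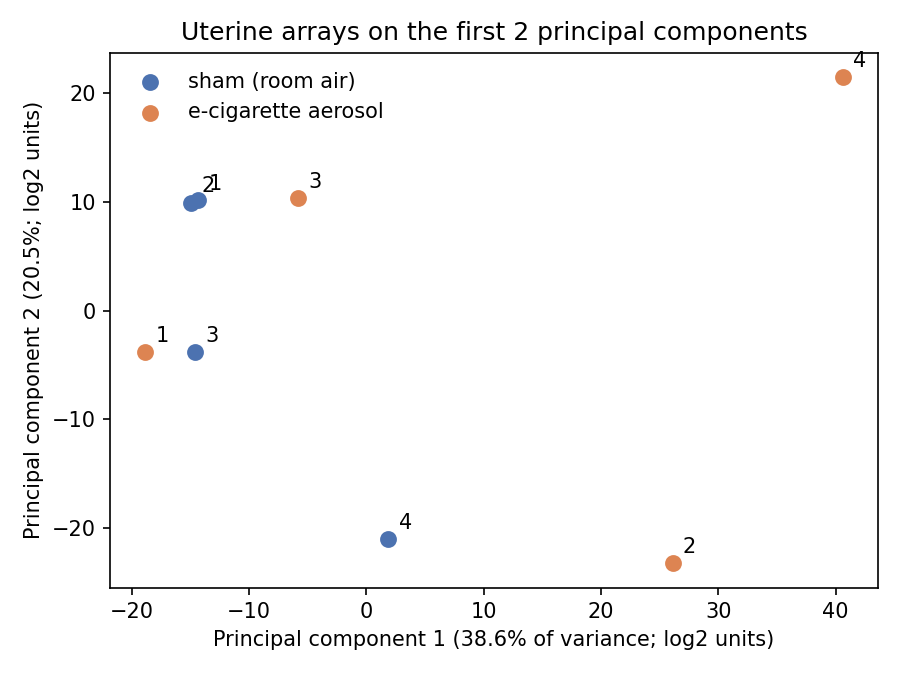
Position of the 8 uterine arrays on principal components 1 (horizontal, 38.6% of variance) and 2 (vertical, 20.5%), both in log2 units over all probe sets, sham in blue and exposed in orange, with the mouse number beside each point. Exposed mice 4 and 2 lie at 40.6 and 26.1 on the horizontal axis, and the other 6 between -18.8 and 1.85.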

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

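Of the tests in this part, the counts over other divisions of the mice were fixed in advance for probe sets and lists, and all tests on the clock genes, the spread, the proliferation and respiratory chain lists and the adipocyte markers were chosen after the result was seen. In 21 of 364 groups of 4 mice, 1 mouse lay far from the other 3 by Dixon's test, which chance gives in about 1 of 20 groups. Exposed mouse 4 accounts for 6 of the 21 and sham mouse 4 for 5.

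Among exposed mice, mouse 4 stood apart for Rrp12 (6.17, others 6.84 to 6.97), Bmp7 (6.58, others 7.31 to 7.40), Upk3b (7.40, others 7.83 to 7.90), Itgax (6.42, others 5.57 to 5.70), Inha (7.97, others 7.35 to 7.45) and the list of aryl hydrocarbon receptor targets and foreign compound genes (7.21, others 7.03 to 7.06). Exposed mouse 3 stood apart for Tslp (5.33, others 5.59 to 5.62) and Snap25 (5.26, others 4.58 to 4.68), mouse 1 for Sgk1 (9.23, others 7.67 to 7.76), and mouse 2 for Akr1c18 (4.82, others 4.69 to 4.70).

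Among sham mice, mouse 4 stood apart for Muc1 (11.01, others 9.73 to 9.81), Ccl21a (10.20, others 9.84 to 9.89), Gap43 (7.49, others 7.65 to 7.68), Asns (9.26, others 9.73 to 9.81) and Egln1 (10.01, others all 9.93). Sham mouse 3 stood apart for Sox17 (9.52, others 9.21 to 9.25), Vcan (9.81, others 9.30 to 9.36) and H2-DMa (6.29, others 6.82 to 6.89), mouse 2 for Snap25 (5.19, others 4.87 to 4.88) and Akr1a1 (10.36, others 10.27 to 10.28), and mouse 1 for Ccr3 (5.03, others 4.60 to 4.67).

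Across the 35 divisions of the 8 mice into 4 and 4, the real one included, chance cannot be excluded for the counts that could be tested. The number past the adjusted p tests nothing, since the real count is 0 and all 35 reach it (highest other 6). At least as many probe sets passed the unadjusted p in 11 (real 1203, highest other 2895) and the unadjusted p with 1.5-fold in 10 (real 112, highest other 466). At least as many lists passed camera in 29 (real 7, highest other 16), and as large a ratio of median SDs arose in 4 (real 1.31, highest other 1.33). The highest counts of probe sets, 2895 and 466, came from sham mice 1, 2 and 3 with exposed mouse 1 against the other 4. This division differs from the real one only in that exposed mouse 1 and sham mouse 4 change places. It therefore overlaps with exposure and cannot show a structure of the mice apart from their groups. The next highest counts, 2748 and 334, came from sham mice 1 and 2 with exposed mice 1 and 3 against the other 4. That division has 2 sham and 2 exposed mice on each side, so exposure does not set its sides apart. Differences between the mice other than exposure thus gave higher counts than the real groups.

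For the clock genes, chance cannot be excluded, since in 7 of the 35 divisions some list has as many members past the adjusted p over the list alone (real 7, highest other 19). The clock list itself reaches 7 members in the real division alone (highest other 5), a count on which the list was singled out. On the clock contrast (-0.80 ± 0.15 in sham mice), exposed mice 1 and 3, which do not stand apart on the first component, exceeded the sham mean by 0.494, with mouse 1 (-0.58) barely above the highest sham mouse (-0.62), so the test cannot tell whether mice 2 and 4 carry the difference. Exposed mice 3 and 4 had adipocyte scores of 5.90 and 6.16, below the highest sham mouse (6.26). Their clock contrast exceeded the sham mean by 0.844, which excludes fat tissue on mice 1 and 2 as the only source. A contribution of fat stays open. Exposed mouse 2 had the highest contrast (0.889) and adipocyte score (6.96), and without it the group difference was 0.638 instead of 0.902. Exposed mouse 1, however, had the next highest adipocyte score (6.62) and the lowest contrast of the exposed mice (-0.58). A different hour of collection could shift the clock genes, exposure could as well, and the design cannot tell them apart, since 0 samples have an hour in the labels.

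For the lower proliferation and respiratory chain genes, exposed mice 1 and 3 alone gave a mean change of 0.111 over the 2 lists, so the lower means lie in the 2 mice that stand apart. Exposed mice 2 and 4 had the lowest exposed scores on both lists, so leaving them out had to raise the mean. The value of 0.111 comes largely from the proliferation score of exposed mouse 1 (0.43 above the sham mean). Noise shared by the genes on the arrays of mice 2 and 4 stays open. Chance is not excluded, as 12 of 35 divisions give as large a change (real 0.233, highest other 0.404, as sizes). Exposure acting on all 4 mice is not borne out by mice 1 and 3, and whether mice 2 and 4 responded to exposure or differed for another reason was not tested.

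For the adipocyte markers, 6 of 12 (Adipoq, Plin1, Cidec, Fabp4, Retn and Scd1) lay above all other mice in both exposed mouse 1 and exposed mouse 2, against 2.84% of all genes. Fat tissue carried along with the uterus would give this, and a response of these 2 mice to exposure was not tested.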

How the results depend on the processing

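The 3 settings that leave out several mice were chosen after the data were seen, and all other tests in this part were planned. No probe set passed the adjusted p under quantile normalization, median centring, either expression filter, other variance settings, array weights or the replicate number as a block. The first 2 moved no count, which was settled beforehand because the deposited columns already shared a common distribution. Without probe sets below the median, 796 passed the unadjusted p and 70 also 1.5-fold, with fewer probe sets tested, and with no moderation 41 passed both. With an estimated correlation 0 lists passed (2 at unadjusted p) and with fry 0 (3 at unadjusted p). The median over markers gave 1 cell type, smooth muscle, lower (exact permutation p = 0.0286, adjusted 0.486). Leaving out each mouse in turn gave 0 to 1 probe sets past the adjusted p (the 1 without exposed mouse 1), 726 to 2545 at unadjusted p, 59 to 462 with 1.5-fold, 5 to 12 lists, 0 cell types and a separation of -2.20 to 6.83. Over these fits, immediate early genes ran from -0.206 to 0.171 (higher without sham mouse 1) and natural killer cell markers from -0.136 to 0.211 (lower without exposed mouse 4). Of 40 list means, 36 moved over 1.5 times in at least 1 of these fits and 18 changed sign, 0 of the 18 among the 7 called lists.

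Without exposed mice 2 and 4, 55 probe sets passed unadjusted p and 1.5-fold, the separation was -0.969, and the proliferation (0.209) and respiratory chain (0.0140) lists turned direction. Without exposed mice 1 and 2, 7 probe sets passed the adjusted p, 1950 the unadjusted p and 440 also 1.5-fold, and the unfolded protein response list turned direction (0.178). Without sham mouse 4 and exposed mice 2 and 4, 58 probe sets passed unadjusted p and 1.5-fold, 3 lists passed and proliferation turned direction (0.144). Apart from the smaller sets of probe sets or mice, the cause was not tested. Of 19 alternatives, the clock list kept its call and direction in 17, foreign compound genes in 16, respiratory chain in 15, proliferation and collagens in 13 each, progesterone-responsive genes in 11 and smooth muscle in 9. No list kept its call with an estimated correlation or with fry. All other alternatives reuse camera's preset correlation of 0.01, with which 29 of 35 divisions gave at least as many lists, so a kept call says little. Quantile normalization, 1 of the 19, could hardly change a call in columns that already shared a distribution. Of 3418 pairs of a named gene and a setting, 39 changed direction, in 26 genes, and 1 passed the adjusted p (Per3). Replicate numbers do not pair the mice (1 of 8 correlates best with its own number), and as a block they gave 1274 probe sets at unadjusted p, 158 with 1.5-fold and 8 lists. The paired form of the cell type scores was not run, since 4 pairs cannot give a p below 0.125. Signal over background was not assessed.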

Other observations

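In this part, the genes, the score correlation and the ribosome assembly list were chosen after values were seen, and the result of the test on the ribosome list was not seen before that list was written. Some genes differed strongly between single mice. Exposed mouse 4 had high Prss28 (12.64, others 4.51 to 6.80) and Prss29 (12.04, others 6.68 to 8.04), which encode implantation serine proteases, and Spink1, a protease inhibitor (12.22, others 6.04 to 9.66). Sham mouse 4 and exposed mouse 2 had the highest Lcn2 (11.79 and 10.08) and Clca1 (10.17 and 9.30). The endocytic receptor Lrp2 was low in sham mouse 4, exposed mouse 2 and exposed mouse 4 (7.31, 7.41 and 6.43, others 9.64 to 10.36), as was Acod1, which makes itaconate (6.51, 4.74 and 6.20, others 7.86 to 9.13). Sectm1b stood at 8.93 and 9.13 in exposed mice 3 and 4 and at 4.78 to 5.34 in the other 6.

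Cldn10, a tight junction gene, passed the adjusted p when exposed mouse 1 was left out (log2 change 1.11, limma adjusted p = 0.0233). Without exposed mice 1 and 2, limma passed Sectm1b (4.02), Hp (3.02), Elapor1 (2.44), Slc5a8 (2.44), Slc39a8 (1.79), Per3 (1.28) and Cldn10 (1.09). That setting was chosen after the data were seen and leaves 2 exposed mice. None of these genes passed with all 8 mice. Sectm1b was low in exposed mice 1 and 2 (5.06 and 4.90), so leaving them out brings its pass about.

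A first hypothesis was that genes of ribosome assembly are lower with exposure as a group. Of 34 measured members, 29 had lower means (mean change -0.21), and the exact permutation p of the list mean was 0.0571, so the test cannot tell. Camera gave an unadjusted p of 2.67e-11, and the unadjusted p was 0.0644 with an estimated correlation. Without exposed mice 2 and 4 the mean change was -0.12.

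A second hypothesis was that progesterone-responsive and proliferation genes follow a shared hormonal state of each mouse. Their scores, which share 0 members, correlated over the 8 mice with a Spearman rho of 0.905 and a Pearson r of 0.865 (exact permutation p = 0.00603, 0.0783 after adjustment over 39 relations), so the test cannot tell. Without exposed mice 2 and 4 the Pearson r was 0.660. Hormone levels were not used here, and the proliferation score correlated more closely with the respiratory chain score (Pearson r 0.922).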
